A study of Mus musculus with 18 samples.

How the data were processed

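Brain RNA of male BALB/cOlaHsd mice was measured on one-colour Agilent arrays (RNA labelled with the dye Cy3), 1 array per mouse. The labels name 18 mice in 6 groups of 3, and they describe the replicates as separate animals of a group of 12. Each sample was placed in its group by its title. The source names of the POS samples carry the code POC beside the same wording of organic potatoes under storage, and the descriptions of the organic samples use the codes PB and PBS. POS replicate 3 is described with a day 27 time point where all others carry day 20.

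The values of the 18 arrays are intensity values that the authors deposited in 1 table of 12439 features, as whole numbers except for 6178 values ending in a decimal 0.5 in the column of PO replicate 2. Agilent Feature Extraction was used, per the submitters' processing notes; its version, the background correction and the choice of features are not given in the sources used here. Some deposited values lie at or below 0, the highest is 65535, and the medians of the 15 arrays used spread over 1.21 on the log2 scale. From these facts the values were read as background-subtracted linear intensities with no scaling between arrays. The authors also deposited a table of 51 named genes with log2 fold changes of each array over the controls; per the file headers, changes between 0.5-fold and 2-fold were set to 0. Recomputation from the value table gave the same log2 fold as deposited, within a tolerance of 1e-06, for all 51 genes on PCS replicates 1 and 2 and POS replicates 1 and 2, as the value over the mean of the 3 controls with no scaling. In that table the entries for PCS replicate 3 and POS replicate 3 equal, within the same tolerance, the log2 of the mean fold of replicates 1 and 2. Of the 204 entries on those 4 arrays, 13 lay within the 2-fold limit and were not 0. How the 51 genes were chosen, and any test used, is not given in the sources used here.

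3 of the 18 columns were left out after the columns had been examined. The column of PO replicate 2 equals the mean of PO replicate 3 and PCS replicate 1 in all 12439 features. The columns of PCS replicate 3 and POS replicate 3 correlated negatively with every other array used (r from -0.17 to -0.14 over log2 values of features), and with each other at r = 0.97. The remaining 15 arrays gave 3 mice each for water control, ADI and PC and 2 each for PO, PCS and POS. The design fixed before the data were examined used all 18 arrays, and the fit on all 18 columns is therefore an added alternative.

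Each array was scaled to a common 75th percentile, values below 16 were set to 16, and the log2 was taken. The number of features set to 16 was 8 to 40 per array, and 145 on POS replicate 2. All 15 arrays entered a single fit of group means with limma 3.58.1 in R 4.3.3 (lmFit and eBayes), and p-values were adjusted by Benjamini-Hochberg over all features at a threshold of 0.05. 12 comparisons were made. A check of overlap between comparisons with the same controls used 20 simulated draws of unchanged groups. Fold changes are group differences of mean log2 values, given with the standard error (SE) of that fit, while group levels are means of scaled intensity with the SD. The files give no detection or saturation flags, so no feature was set aside as undetected, and the number of arrays limits the precision.

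Only the 51 listed features are paired with a gene name; of their accessions 46 matched the mouse RefSeq table of assembly GRCm38.p6, with no changed symbol. The files name no genome build, and no coordinates are given. All other features are reported by number. 44 gene lists were fixed before the data were examined. None had the 5 named members that a list test needed, so no list test was run, and the only list members with a name were Vgf and Cpne4. Named genes followed a rule set at the same time. Where fewer than 10 features passed, it took those with the smallest unadjusted p among features with at least a 1.5-fold change and groups that do not overlap. It also provided for members of the fixed lists that passed adjustment over their list alone, and for the genes with the largest entries in the authors' deposited table, up to 10 per comparison. Vgf and Cpne4 were taken as list members without that adjustment, and both are also among these largest entries.

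The replicate numbers were checked for pairing through correlations of residuals from the group means. Same-numbered arrays of control, ADI and PC ran together (control and ADI, r from 0.21 to 0.33; control and PC, r from 0.15 to 0.30). The fit was tested on simulated data with 200 changed features among 12439. It recovered 43.0% of 2-fold and 82.0% of 4-fold changes for ADI against control, 44.5% and 85.5% for PC against control, and 28.0% and 80.5% for PCS against control. The simulated noise was drawn independently on each array with the spread of the fit. It held no local deviations of a single array and no pairing by replicate number, so these shares need not hold for the real arrays.

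Alternatives fixed before the data were examined were quantile normalization, centring on the median, dropping the dimmest 25% of features, a trended robust variance, the compared groups alone, array weights, the replicate number as a block, each array left out in turn, and an unadjusted threshold with a 1.5-fold change. Alternatives added after seeing the data were no scaling, all 18 columns, removal of the local trend over the array surface, an offset of 50 in place of the lower limit of 16, and leaving out POS replicate 2 with the block or, where POS is not compared, alone. For ADI and PC the block with the compared groups alone was also added. The local trend was the median deviation of neighbouring features in a window of 17 by 17 positions, with positions taken from feature numbers in rows of 85. The layout of the array is not given in the sources used here, and 85 was inferred from the correlation of deviations over feature numbers. Plots were drawn in Python 3.11.15 with matplotlib 3.10.9.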

Results

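The study asked how potato flour from conventional or organic cultivation, with or without storage, and a pesticide mixture alter gene expression in the mouse brain. Male mice aged 8 weeks at the start were gavaged daily for 20 days. Controls received water, and the ADI group received 9 pesticides mixed, each at its acceptable daily intake, the dose judged safe for daily consumption. The other groups received 30 mg per day of flour from whole tubers. PC and PO stand for conventionally and organically grown potatoes, and PCS and POS for the same potatoes under storage conditions.

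Array brightness separated the 4 stored-potato arrays used from the other arrays used. The 75th percentile of intensity lay between 838.5 and 1079 on the 11 arrays of control, ADI, PC and PO, and between 1531 and 1995.5 on the 4 arrays of PCS and POS. The ratio of the geometric means was 1.70. Over features, 14 of the 15 arrays correlated with each other at r = 0.97 to 0.98 on the log2 scale, whereas POS replicate 2 correlated with them at r = 0.83 to 0.85. Features are not independent replicates, and these r values describe the arrays only.

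**Figure D1:**
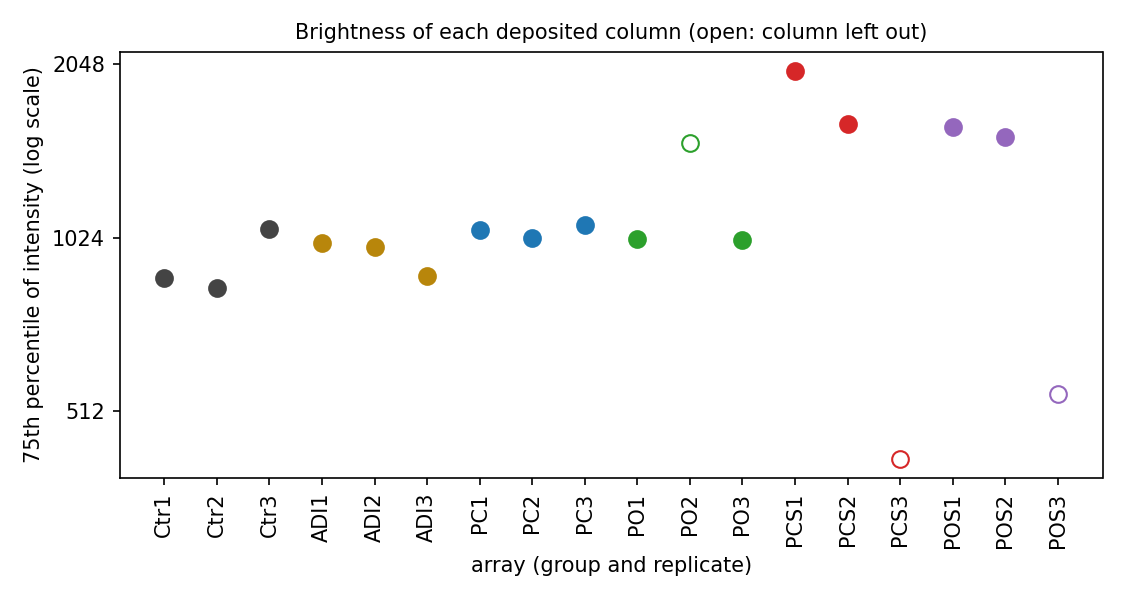
The 75th percentile of deposited intensity (vertical axis, log scale) is plotted for each column, coloured by group; open circles are the 3 columns left out of the tests. The 4 filled points of PCS and POS, from 1531 to 1995.5, all lie above the 11 filled points of the other groups, which reach 1079.

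The authors' deposited table lists 51 genes, all with entries other than 0 in both PCS and POS. 48 have positive entries and 3 negative ones. Ppp1r18, a regulatory subunit of protein phosphatase 1, Tulp4, a tubby-like protein, and Adgb, the globin androglobin, carry the negative entries. By the authors' grouping, 23 genes relate to carcinogenesis, 10 to the immune system, 6 to the reproductive system, 5 to the nervous system, 2 to its development and 3 to metabolism. The cardiovascular and muscle groups hold 1 gene each. No gene has an entry other than 0 in ADI or PO, and 1 gene has in PC. The list was chosen by the authors on these same arrays, so its counts are not independent evidence of a change.

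The ADI comparison asked whether the pesticide mixture alone changed brain expression. The median log2 change of the 48 listed genes with positive entries was 0.05. Phldb2, a pleckstrin homology domain protein, had 2.02 ± 1.20 (SE) and Olfr1278, an olfactory receptor, 1.46 ± 0.77, each against controls that included a single low deposited intensity, of 4 and 62; neither passed (limma, adjusted p 1.00). Zfp37, a zinc finger protein, had a scaled intensity of 1261 ± 704 (SD, n = 3) against 1306 ± 543 (SD, n = 3) in controls. Vgf, a neuropeptide precursor induced by nerve growth factor, had 454.9 ± 82.6 against 453.1 ± 46.6, and Cpne4, a calcium-dependent phospholipid-binding protein, had 1139 ± 260 against 1065 ± 317. Among unnamed features, number 14919 had 72.0 ± 6.92 against 21.5 ± 4.97 in controls and number 41233 had 20.1 ± 4.04 against 67.2 ± 7.23, both at the dim end of the arrays. By limma, 0 of 12439 features passed (smallest adjusted p 1.00), and 196 had an unadjusted p under 0.05, fewer than the 621.95 that chance gives for independent features. The 95% interval of a feature's change had a median half-width of 0.52 on the log2 scale. Groups did not overlap for 4.96% of features, where chance gives 10% for 3 against 3. Both chance values take the arrays as independent, whereas same-numbered control and ADI arrays deviated together (r from 0.21 to 0.33). They are thus no exact measure of chance here. The SE also rests on the residuals of all 15 arrays, POS replicate 2 included, which is outside this comparison. Its deviations can widen the interval and lower the count here and in the other comparisons without POS.

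PC against control asked the same of flour from conventional potatoes. The authors' deposited table holds a single gene for it, Phldb2, placed in the carcinogenesis group, with log2 entries of 1.14, 0.90 and 1.00. Its scaled intensity was 1221 ± 148 (SD, n = 3) in PC and 772.5 ± 664 (SD, n = 3) in controls. Control replicate 3 had a deposited intensity of 4, where the other controls had 968 and 773. The log2 change of Phldb2 was 2.14 ± 1.20 (SE) and did not pass (limma, adjusted p 1.00), and in PO it was 2.09 ± 1.34. The median over the 48 listed genes was 0.05 in PC. Unnamed feature 28575 had 23.7 ± 7.51 against 67.0 ± 9.18 in controls (limma, adjusted p 0.0795) and feature 4834 had 109.1 ± 8.44 against 63.9 ± 4.60. No feature of 12439 passed by limma, with 170 at an unadjusted p under 0.05. Without PC replicate 1, and likewise without PC replicate 2, the count was 1, and with array weights it was 2.

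PO against control rested on 2 PO mice. The median log2 change of the 48 listed genes was 0.02. Olfr1183, an olfactory receptor, had a scaled intensity of 1010 ± 84.2 (SD, n = 2) against 983.7 ± 217 (SD, n = 3), and Rbfox2, an RNA-binding splicing regulator, had 1107 ± 2.81 against 1180 ± 197. Unnamed feature 4834 had 107.8 ± 24.9 against 63.9 ± 4.60, and feature 16821 had 42.8 ± 13.3 against 98.0 ± 5.58. 0 of 12439 features passed by limma (smallest adjusted p 0.647), and 285 had an unadjusted p under 0.05. Groups did not overlap for 19.5% of features, where chance gives 20% for 3 against 2. The low count of 285 thus came without a low share of separated groups, and the SE here also rests on all 15 arrays. Leaving out PO replicate 1 gave 1 feature and leaving out PO replicate 3 gave 2.

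PCS against control addressed stored conventional potatoes. Zfp37 had the largest positive difference of the listed genes, at 12899 ± 11467 (SD, n = 2) against 1306 ± 543 (SD, n = 3), a log2 change of 3.02 ± 0.79 (SE) and an 8.10-fold difference. Ppp1r18 had 4966 ± 4067 against 52843 ± 16656, Tulp4 4510 ± 3921 against 54466 ± 17584 and Adgb 4033 ± 3453 against 54883 ± 17066. Their log2 changes were -3.65 ± 0.63, -3.88 ± 0.68 and -4.04 ± 1.15 (SE). Both PCS mice lay beyond every control in these directions, and none of the 4 genes passed over all features (limma, adjusted p 0.668 for Zfp37, 0.205 for Ppp1r18 and Tulp4 and 0.668 for Adgb). Ppp1r18, Tulp4 and Adgb passed over all features with array weights, and all 4 passed with no scaling and with the replicate block and POS replicate 2 left out. Without PCS replicate 1 the log2 changes were 1.95 for Zfp37, -2.70 for Ppp1r18, -2.84 for Tulp4 and -3.03 for Adgb, and without PCS replicate 2 they were 4.08, -4.60, -4.91 and -5.05.

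The remaining listed genes differed less between PCS and control once arrays were scaled. In the authors' deposited table the 48 positive genes had a median log2 fold of 1.55 in PCS, and every one of the 51 lay beyond 2-fold. In the fit on scaled arrays their median was 0.58, a 1.49-fold difference. Without scaling, the median of all 12439 features was itself above control on the log2 scale, by 0.93 in PCS and 0.80 in POS, and 2994 features were at least 2-fold higher in both PCS and POS. After scaling this number was 20. The carcinogenesis group had a median of 0.57 over its 22 positive genes. Within it Cpne4 had 1828 ± 334 against 1065 ± 317 in controls and Sh3gl2, endophilin A1 of synaptic vesicle endocytosis, had 1062 ± 313 against 621.0 ± 23.7. The immune group had a median of 0.52 over 10 genes, among them Zbtb37 at 859.4 ± 119 against 515.3 ± 85.4. Of the nervous system genes, Olfr1183 had 1719 ± 165 against 983.7 ± 217 and Olfr1278 had 1596 ± 37.8 against 817.0 ± 640, with a single low control of deposited intensity 62. The reproductive group, with a median of 0.67 over 5 positive genes, included Vmn1r20, a vomeronasal receptor, at 1912 ± 98.2 against 1196 ± 438.

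Unnamed feature 10961 had 152.1 ± 4.11 in PCS against 21.4 ± 2.09, and feature 36627 had 3182 ± 2430 against 19739.5 ± 7940. Feature 12646, first by p among lower features, was at the ceiling of the scale on both PCS arrays, so its level there is only a lower bound. Its scaled level in controls, 79664 ± 9462 (SD, n = 3), also lay near where scaling puts the ceiling. The scaling of the brighter PCS arrays therefore enters this difference. By limma 0 of 12439 features passed for PCS (smallest adjusted p 0.205), and 829 had an unadjusted p under 0.05. Adjusted over the list alone, 6 of the 51 genes passed, 3 higher (Zfp37 and, named after their values were seen, Synm and Sema4f) and 3 lower (Ppp1r18, Tulp4 and Adgb). That number was 0 without PCS replicate 1, 2 without control replicate 1 or 2, 3 without control replicate 3 and 32 without POS replicate 2. With no scaling between arrays 8756 features passed, 8750 of them higher in PCS. Groups did not overlap for 29.7% of features, where chance gives 20% for 3 against 2.

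**Figure D2:**
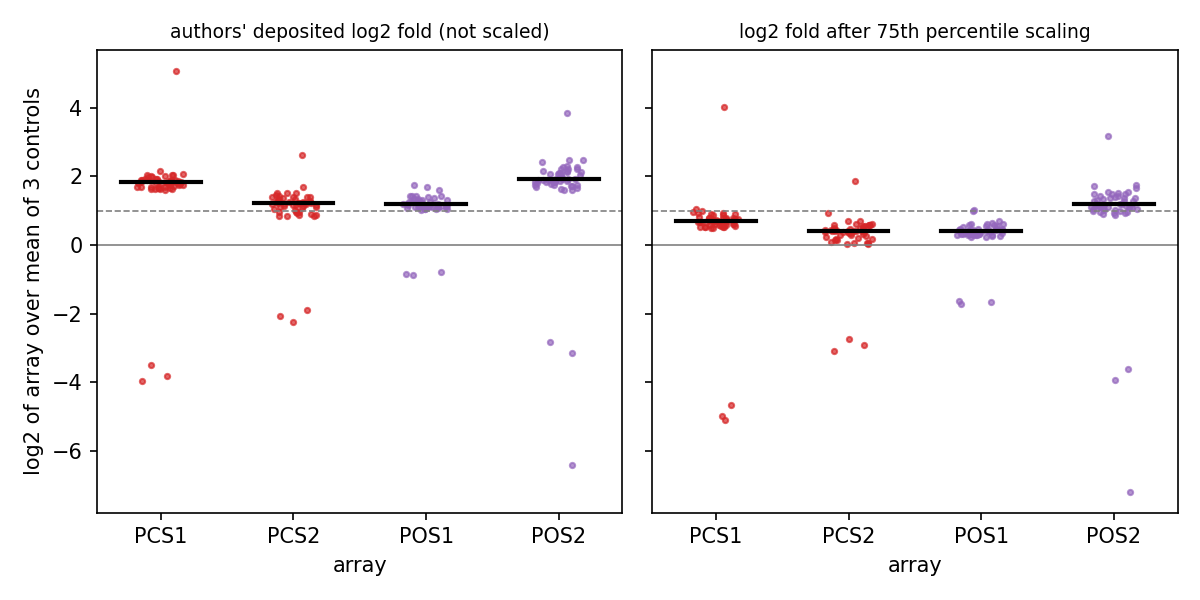
Each point is a listed gene, as the log2 of its value on an array over the mean of the 3 controls (vertical axes); the left panel holds the authors' deposited values, the right panel the same arrays scaled to a common 75th percentile, and bars are medians of the 48 genes with positive entries. After scaling the medians were 0.70, 0.40, 0.40 and 1.19 on PCS replicates 1 and 2 and POS replicates 1 and 2, and the dashed line marks 2-fold.

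POS against control addressed stored organic potatoes. Zfp37 had 7203 ± 6452 (SD, n = 2) against 1306 ± 543 (SD, n = 3), a log2 change of 2.17 ± 0.79 (SE). Ppp1r18, Tulp4 and Adgb had log2 changes of -2.55 ± 0.63, -2.73 ± 0.68 and -4.39 ± 1.15, with both POS mice below every control. Leaving out POS replicate 2 moved these values to 1.09 for Zfp37, -1.57 for Ppp1r18, -1.60 for Tulp4 and -1.65 for Adgb. Leaving out POS replicate 1, so that POS replicate 2 stood alone for the group, moved them to 3.25, -3.54, -3.86 and -7.13. With no scaling all 4 genes passed over all features. Adgb lies in inferred array rows 426 to 478, where POS replicate 2 had a median deviation of -1.20 on the log2 scale. Phldb2 had 2.34 ± 1.34, with the same single low control. The 48 positive genes had a median log2 change of 0.84, against 1.62 in the authors' deposited table. Vgf had 991.4 ± 404 against 453.1 ± 46.6, Agap1, a GTPase-activating protein for Arf, had 1517 ± 948 against 647.9 ± 60.1, and Gatad2a, a subunit of the NuRD chromatin remodelling complex, had 2524 ± 1428 against 1108 ± 280. Rbfox2 had 2630 ± 1166 against 1180 ± 197, and Traf5, a TNF receptor-associated signalling factor, had 4374 ± 2459 against 2109 ± 281. The POS mice lay apart: the median of the 48 genes was 0.40 on POS replicate 1 and 1.19 on POS replicate 2. On POS replicate 2 the features around the listed genes, none of them listed, also had a median deviation of 0.49 on the log2 scale, and on POS replicate 1 of 0.

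Unnamed feature 15252 had 322.1 ± 72.5 in POS against 150.7 ± 22.5, and feature 37268 had 126.5 ± 54.4 against 418.6 ± 17.7. Both lie where POS replicate 2 deviated in the same direction. Its median deviation was 0.50 on the log2 scale in inferred rows 160 to 212, which hold feature 15252. In rows 426 to 478, which hold feature 37268, it was -1.20. By limma 0 of 12439 features passed for POS (smallest adjusted p 0.0614), and 3451 had an unadjusted p under 0.05. Adjusted over the list alone 48 of the 51 genes passed, 45 higher and 3 lower, and without POS replicate 2 none did. Without POS replicate 1 the fit called 5102 features, 2403 higher and 2699 lower, and without POS replicate 2 it called 0. In each of these fits a single POS array stood for the group. Without POS replicate 1 the local deviations of POS replicate 2 enter the count as differences. Groups did not overlap for 28.6% of features, where chance gives 20% for 3 against 2.

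**Figure D3:**
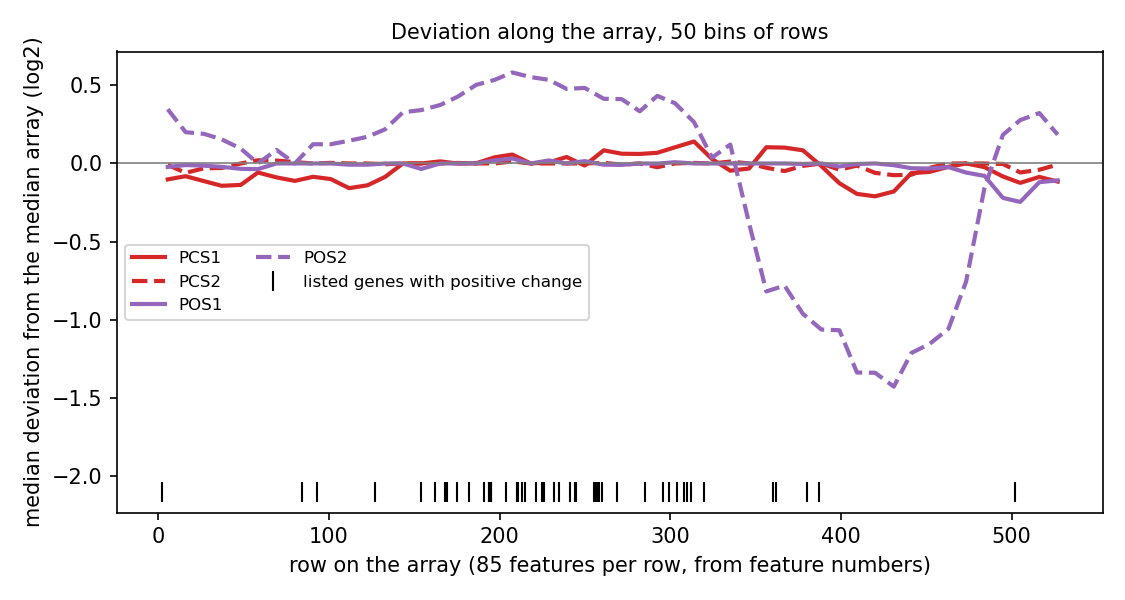
The median log2 deviation from the median array (vertical axis) is drawn along 532 inferred rows of the array (horizontal axis, feature number in rows of 85) for PCS and POS replicates 1 and 2, and black ticks mark the 48 listed genes with positive entries. The line of POS replicate 2 had a median of 0.50 in rows 160 to 212 and -1.20 in rows 373 to 425, and 37 of the 48 ticks lie in rows 160 to 319.

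**Figure D4:**
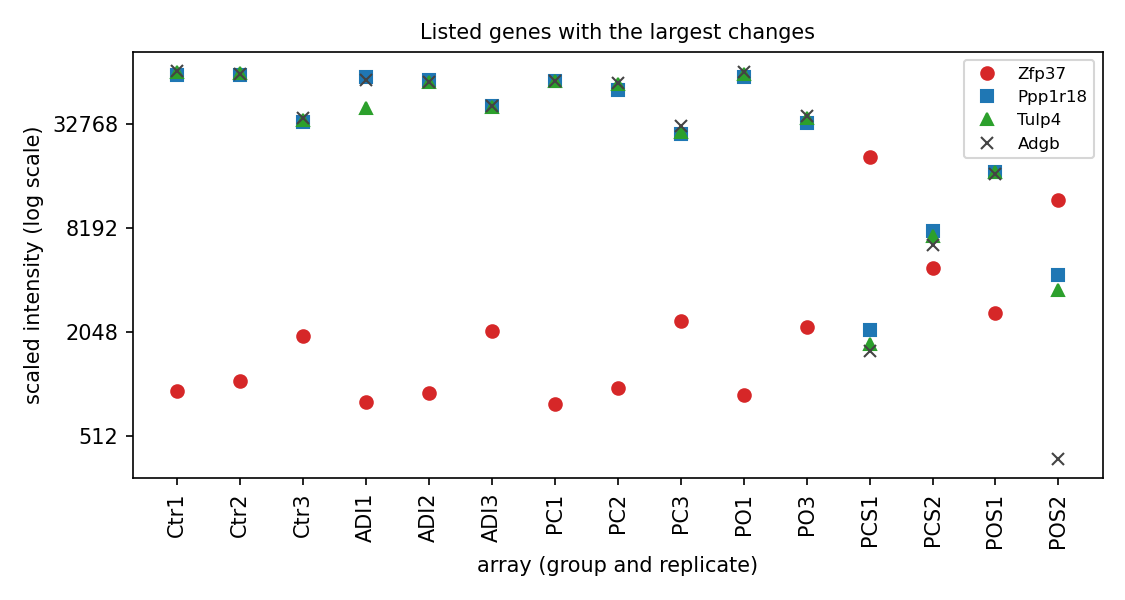
Scaled intensity (vertical axis, log scale) of Zfp37, Ppp1r18, Tulp4 and Adgb on each of the 15 arrays used. Zfp37 lies highest on PCS replicate 1, and the other 3 genes lie within a log2 range of 0.58 of each other on every array except POS replicate 2, where the range was 3.53.

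PC against PO and PCS against POS set conventional beside organic potatoes. Without storage, Zfp37 had 1369 ± 859 (SD, n = 3) in PC and 1538 ± 923 (SD, n = 2) in PO, and Cpne4 had 1107 ± 317 and 929.2 ± 29.8. With storage, the log2 change of PCS over POS was 0.85 ± 0.86 (SE) for Zfp37, -0.52 ± 0.26 for Vgf and -1.09 ± 0.69 for Ppp1r18. These values rested on single mice: Zfp37 had -0.22 without PCS replicate 1, 1.91 without PCS replicate 2, -0.23 without POS replicate 1 and 1.93 without POS replicate 2. In the same order Ppp1r18 had -0.14, -2.05, -0.11 and -2.08, and Vgf had -0.95 without POS replicate 1 and -0.095 without POS replicate 2. None of the 51 genes passed in either comparison, over all features or adjusted over the list alone. By limma 0 features passed in both, with 169 at an unadjusted p under 0.05 for PC against PO and 1676 for PCS against POS. Averaged over storage the comparison called 0 features, with 615 at an unadjusted p under 0.05 and a smallest adjusted p of 0.666. Without POS replicate 1 the counts were 3954 for PCS against POS and 2993 for the average over storage, and without PCS replicate 1 PCS against POS gave 2. PC against PO gave 1 feature without PO replicate 1 and 2 without PO replicate 3.

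PCS against PC, POS against PO and their average addressed storage itself. Averaged over cultivation, Zfp37 was higher with storage by 2.52 ± 0.58 (SE) on the log2 scale, and Ppp1r18, Tulp4 and Adgb differed by -2.90 ± 0.47, -3.13 ± 0.50 and -4.07 ± 0.85. Gatad2a differed by 1.00 ± 0.25, Rbfox2 by 0.90 ± 0.22 and Traf5 by 0.60 ± 0.22. Without POS replicate 2 the difference was -2.70 for Adgb and 0.30 for Traf5, and without POS replicate 1 it was -5.44 for Adgb and 0.91 for Traf5. These values did not pass over all features (limma, adjusted p 0.0770 for Ppp1r18 and Tulp4, 0.102 for Adgb, 0.127 for Zfp37, Gatad2a and Rbfox2 and 0.174 for Traf5). Adjusted over the list alone, 46 of the 51 genes passed for the average, 4 for PCS against PC and 44 for POS against PO, with the same reservation about how the list was chosen. Limma called 0 features for the average (smallest adjusted p 0.0770), 0 for PCS against PC and 0 for POS against PO, with 2683, 672 and 3029 at an unadjusted p under 0.05. Left-out arrays moved these counts: without POS replicate 1 the average gave 4547 and POS against PO 4812. PCS against PC gave 2 without PCS replicate 1, and the average gave 6 without PCS replicate 2, 2 without PO replicate 3 and 1 without POS replicate 2. POS against PO gave 1 without PO replicate 1 and 2 without PO replicate 3. All 4 stored-potato arrays were also the brightest used, so storage and any set of arrays processed together cannot be told apart.

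The interaction asked whether the difference between conventional and organic potatoes depended on storage. No listed gene passed over all features or adjusted over the list alone (smallest adjusted p over the list 0.748). Limma called 0 of 12439 features, with 509 at an unadjusted p under 0.05. Its 95% interval had a median half-width of 0.86 on the log2 scale, the widest of the 12 comparisons. The count was 2929 without POS replicate 1 and 1 without PO replicate 3.

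The 5 comparisons with water share the same 3 controls. For PCS and POS, 370 features had an unadjusted p under 0.05 in the same direction, against 109.1 in simulated unchanged groups with these controls and 121.9 for independent lists of those lengths. The covariance of their log2 changes was 0.105, against a simulated 0.0492. Their correlation was close to the simulated value, at r = 0.434 against 0.399. The overlap was 115 without PCS replicate 1, 209 without control replicate 1 and 972 without POS replicate 1. For ADI and PC the overlap was 45 features against a simulated 142.6 and 1.34 for independent lists, and the covariance was 0.0278 against 0.0488. The correlation of these log2 changes was r = 0.531 against a simulated 0.497. The controls were too few to split, so part of any excess over independent lists may come from the shared controls. The simulation drew arrays independently, whereas same-numbered arrays of control, ADI and PC deviated together, so its values are no measure of chance for ADI and PC. Over the pairs other than PCS and POS, the covariance ran from 0.0196 (PO and POS) to 0.0335 (PC and PCS). It lay below the simulated value in each, also where replicate numbers did not run together. The simulated lists need not have the real lengths either. The simulation is therefore no exact measure of chance for PCS and POS.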

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

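All tests in this part were chosen after the values they bear on had been seen. The groups were too small for a check of single samples within a group, and no test of the interaction passed. The left-out columns of PCS replicate 3 and POS replicate 3 were compared with the controls after scaling to the controls' 75th percentile. In them 1743 and 1733 features, in that order, were at least 10-fold above every control. The highest number on any of the 12 treated arrays used was 1. Both columns correlated negatively with every other array used, so the counts cannot tell higher signal from features that do not match between columns. Before scaling, the 75th percentile was 424 in the column of PCS replicate 3 and 548 in that of POS replicate 3. The lowest among the controls was 838.5.

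These columns run against all others feature by feature. Another order of the rows was tested over all shifts of the deposited rows, a limited span of shifts by feature number, the reversed order and the order of feature numbers sorted as text. The highest correlation with the mean of the 15 arrays was 0.068, far under the value that a matching order among these would restore. Longer shifts by feature number were not tried. RNA of another tissue on the same features should keep a positive correlation, since features differ in brightness whatever the sample, and the higher of the correlations was -0.16. Another array layout stays open, since the columns ran with each other at r = 0.97 and no value in the tables decides it. No biological explanation was tested.

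The listed genes stood at least 2-fold above control in PCS and POS in the deposited folds, and array brightness left unscaled is a candidate explanation: after scaling, 3 of the 48 stayed at least 2-fold higher in both by mean log2 values (Zfp37 and, with a single low control value each, Phldb2 and Olfr1278), and 1 by mean intensity over the mean of the controls. Part of what remained in POS may come from a local trend on POS replicate 2. Features around the listed genes, none of them listed, were raised by a median of 0.49 on POS replicate 2, above all of 10000 random lists matched on brightness, where the listed genes themselves stood a median of 1.21 above the mean log2 of controls. The remainder on PCS replicates 1 and 2 and POS replicate 1, where the trend around the same genes was 0.014 or less, stays open, with an effect of storage untested and a difference between array sets inseparable from it. The list was chosen on these same arrays, and all 51 genes had deposited folds beyond 2-fold in PCS and POS. A positive remainder is therefore no independent evidence of a change.

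Zfp37, Ppp1r18, Tulp4 and Adgb kept a difference after scaling, the smallest being 2.17 on the log2 scale for Zfp37 in POS, or 1.09 without POS replicate 2, where the other 3 genes had -1.57, -1.60 and -1.65; brightness alone does not account for the lower values of those 3 on brighter arrays or for Zfp37 in PCS. Ppp1r18, Tulp4 and Adgb read nearly alike, with a median range within an array of 0.10 on the log2 scale while the mean of their deposited log2 intensities moved over 4.54 between arrays, and a target shared by the features may account for this. Saturation at the scanner ceiling does not account for it, because the range reached only 0.39 on PCS replicates 1 and 2 and POS replicate 1, far below the ceiling. On POS replicate 2 the range was 3.53. There Adgb lies in inferred rows 426 to 478, where the median deviation of that array was -1.20. The genes also moved within groups: after scaling, the mean of the 3 genes on replicate 3 lay below replicates 1 and 2 by a log2 difference of -0.90 in controls, -0.91 in PC and -0.41 in ADI, and in deposited values by -0.59, -0.86 and -0.59, so sets of arrays stay open as an explanation. In PO the mean deposited log2 intensity of the 3 genes was 14.94 on replicate 3 and 15.79 on replicate 1. Zfp37 moved the other way. Its deposited intensity on replicate 3 was 1806 in controls, 1608 in ADI, 2245 in PC and 1966 in PO. On replicates 1 and 2 of these groups, among the arrays used, it was 713 to 879. An effect of storage stays open and was not tested apart from such sets of arrays.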

How the results depend on the processing

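Alternatives with no scaling, all 18 columns, the local trend removed, an offset, POS replicate 2 left out with the block and the block within the compared groups were chosen after seeing the data, as were all those for the shared-control overlap. Unless stated, each of the 12 comparisons kept a count of 0. An unadjusted p under 0.05 with at least a 1.5-fold change gave 133 features for ADI, 120 for PC, 169 for PO, 463 for PCS and 2759 for POS against control. It gave 104 for PC against PO, 1419 for PCS against POS, 369 for PCS against PC, 2619 for POS against PO, 235 for cultivation, 1350 for storage and 486 for the interaction. With no scaling the counts were 8756 for PCS, 7412 for POS, 6562 for PCS against PC, 5347 for POS against PO and 8165 for storage, where the shift of whole arrays enters every feature. Quantile normalization gave 3 for POS, 2 for POS against PO and 2 for storage; centring on medians and leaving out dim features gave 1 and 3 for POS. Trended variance gave 1 for PCS, 5 for POS and 1 for storage, array weights 2 for PC and 5 for PCS, the compared groups alone 1 for PCS, the local trend removed 1 for POS and 6 for storage, and the offset 3 for POS and 12 for storage. With the replicate block PCS gave 2 features and no other call changed, ADI and PC included, where the numbers pair the arrays; control and PCS share only numbers (r from -0.13 to 0.04); with the block and POS replicate 2 left out PCS gave 65, PCS against PC 40 and storage 68. The causes were not tested. With 1 array left out in turn, a lone array being assumed to vary like the others, counts ranged from 0 to 1 for PC, 0 to 2 for PO, PCS, PC against PO and PCS against PC, 0 to 5102 for POS, 0 to 3954 for PCS against POS, 0 to 4812 for POS against PO, 0 to 2993 for cultivation, 0 to 4547 for storage and 0 to 2929 for the interaction; the highest counts above 2 came without POS replicate 1. The listed genes' median was 0.58 in PCS and 0.84 in POS in the fit against 1.55 and 1.62 deposited, 1.55 and 1.60 with no scaling, and with all 18 columns -0.30 and -0.10, where the columns of PCS replicate 3 and POS replicate 3 enter. With all 18 columns Olfr1278 (-0.47), Olfr1183 (-1.18), Zbtb37 (-0.26), Vmn1r20 (-0.69) and Traf5 (-1.10) reversed in PCS, and Olfr1183 (-0.54), Zbtb37 (-0.039), Vmn1r20 (-1.35) and Traf5 (-0.57) in POS. Listed genes past the threshold over the list numbered 6 in PCS and 48 in POS; in PCS they were 1 with all 18 columns, 35 with array weights, 27 with the trend removed, 51 with no scaling, 34 with the block and POS replicate 2 left out, and 0 to 32 with an array left out; in POS they were 1 with all 18 columns, 0 with array weights, with the compared groups alone and with the block and POS replicate 2 left out, and 0 to 50 with an array left out. Those at least 2-fold apart in both numbered 6, but 51 with no scaling and 12 with all 18 columns. The shared-control overlap of 370 was 141 with array weights, 7292 with no scaling, 136 with all 18 columns, 570 with the trend removed and 115 to 972 with an array left out. Of 560 values of 16 named genes, 551 kept their direction and 53 went past the threshold, 32 with no scaling and 21 with array weights, with the block and POS replicate 2 left out or without POS replicate 1. Every feature was tested alone. None of the 51 named genes had several features, and for unnamed features this is unknown, so testing each probe alone was no separate alternative. POS replicate 3 was already out, and list tests were not run. Signal over background was not given and limits dim features.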

Other observations

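All tests in this part were chosen after the values they bear on had been seen. The array layout is not given in the sources used here; rows of 85 features, 532 in all, were inferred from the correlation of deviations over feature numbers, so that correlation is no separate evidence of a trend. Between features next to each other by number, which needs no row length, deviations correlated at r = 0.64 on POS replicate 2 and at 0.14 or less on the other arrays. On POS replicate 2 the median deviation from the median array was 0.50 on the log2 scale in rows 160 to 212 and -1.20 in rows 373 to 425. Of the 48 listed genes with positive entries, 37 lay in rows 160 to 319, or 77.1% of them against 32.5% of all features.

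Other splits of the arrays were counted for features at an unadjusted p under 0.05. For ADI against control the real split gave 196, and all 10 splits of the 6 arrays gave as many, the highest other 653. For PC against control it gave 170, again as many in all 10, the highest other 642. 10 splits are too few for a share under 0.05. Replicate numbers pair these arrays: among the 4 splits that part every pair, the real one included, the highest other was 246 for ADI and 250 for PC, while the highest counts came from splits that keep a pair together, which points to a structure of the arrays by replicate number. For conventional against organic potatoes 44 of 100 drawn splits of the 9 arrays gave at least the real 615, with 1803 as the highest other, so chance was not excluded. For stored against not stored 2 of 100 gave at least the real 2683, the real split included, with 2873 as the highest other. That share is under 0.05. The draws shuffled the labels of all 4 groups, so a drawn split can keep the stored arrays together. Whether the draw with 2873 did so was not recorded. That draw therefore neither speaks for chance nor excludes it. The split also follows array brightness.

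Over the 15 arrays, 45 features, these 3 included, followed the mean of Ppp1r18, Tulp4 and Adgb at r above 0.9, and 28 ran against it at r below -0.9, Zfp37 among them at r = -0.97.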
